A study of Drosophila melanogaster with 5 samples.

How the data were processed

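Total RNA from dissected salivary glands was hybridised to 5 Affymetrix 1-colour arrays, 3 labelled as from animals with the heat-inducible fkh transgene and 2 as from w1118 animals, which the titles write as w1118(3) without explanation. RNA was isolated with TRIzol and an RNeasy column and labelled as biotin cRNA with the Affymetrix one-cycle assay, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 per probe set, which the authors made with dChip by normalizing all arrays to 1 baseline array of median intensity 134, per the series' design text. The dChip version, its expression model and its background handling are not given in the sources used here. That the scale is linear was read from the values, which run from 0 to between 15488 and 16327 with medians of 44.5 to 49.3. The baseline array's median is higher than these medians, and what it refers to is not given in the sources used here. A probe set that summarises a bright transcript can approach the top of this range, and its change is then compressed. Low values are compressed by the added constant described next.

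The table holds 18952 probe sets. The 183 control probe sets whose names start with AFFX were left out of the tests. Of the other 18769, the platform annotation gives 1 gene symbol for 13647, several for 402 and none for 4720, which are unnamed here. Of the probe sets with 1 symbol, 13544 matched a gene of the RefSeq gene table of assembly Release 6 plus ISO1 MT, which changed 0 symbols. No genome was used, and no coordinates are given.

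Values were transformed as log2(intensity + 16), so a fold change is on the log2(value + 16) scale and understates the change of dim probe sets. Probe sets were kept when their mean over all 5 arrays lay above the 40th percentile of all non-control probe sets, 5.62 on this scale, which left 11261. No further normalization was applied. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 3 residual and 3.63 prior degrees of freedom), with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. A gene was represented by its probe set with 1 symbol and the highest mean, which gave 8298 genes. Among the called genes, 252 had more than 1 kept probe set. For 144 of these another probe set was called in the same direction and for 17 in the opposite one. The 739 called probe sets with several symbols or none are counted but not named.

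Before the data were examined, 25 gene lists were fixed, and 24 of them had at least 5 kept genes. Each was tested with limma's camera, which compares the genes of a list with all others, at a preset correlation between genes of 0.01 and with adjustment over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way and compares them with no other genes, were run beside it. With an estimated correlation 0 lists passed, and with fry 13. The correlation was estimated with 3 residual degrees of freedom, and the lowest adjusted p that any list then had was 0.64. A miss with that version therefore cannot decide about a single list. Lists whose genes have other names in the annotation were matched through symbols and synonyms, and members with no probe set of 1 symbol were not analysed here.

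The rule for the genes named was also fixed before the data were examined. It takes fkh and white, and the 12 largest rises and 12 largest falls past the threshold whose 3 arrays lie on one side of both controls. It takes up to 4 called genes with the smallest p in each list, or 2 where none was called, and a fixed set of genes of cell death, ecdysone response, autophagy and the gland whatever their p. The text gives a part of the genes that the rule takes. Genes outside the rule are said to have been named after their values were seen. Where a call was lost without any of several arrays, the text gives all these values or 1 of them.

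The procedure was tested on simulated data drawn from the control means and the fitted spread, with the same 3 against 2 design and 11261 probe sets tested. Of the changed probe sets that passed the filter, 3 of 44 were recovered at 1.5-fold, 25 of 45 at 2-fold, 32 of 34 at 4-fold and 32 of 32 at 16-fold. None had the wrong sign, and 9 unchanged probe sets were called. These 9 are a larger share of the simulated calls than the adjusted p threshold allows on average. The changed probe sets were few among the 11261, whereas 39.4% of probe sets were called in the data. The Benjamini-Hochberg cutoff depends on the share that changed, so these rates describe the simulation and do not give the recovery in the data. A list shifted 2-fold in a further simulation was called, with 0 other lists. Alternatives to the constant, the filter, the scaling, the variance model, the pairing by replicate number, the probe set per gene and the arrays used were computed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.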

Results

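RNA was measured in salivary glands of Drosophila melanogaster prepupae, the larval secretory glands that are lost during metamorphosis. The arrays fall into 2 groups. For 3 arrays the labels state glands of animals that carry P{hs-Fkh111}, a heat-inducible transgene of fork head (fkh), which encodes a forkhead-domain transcription factor of the salivary gland. For the other 2 they state glands of w1118 animals, a white-eyed laboratory strain used as the control, which the sample titles write as w1118(3). All animals were grown at 25 °C, heat shocked for 30 min at 37 °C at 9.5 h after puparium formation, and dissected at 14 h. The series title asks which genes respond to Fork head in the glands of late prepupae, and 1 comparison addresses it. The number of arrays limits the precision: an exact permutation test of 1 value with 3 against 2 arrays, with the one-sided p doubled, cannot give a p below 0.2. The submitters call the samples of each group biological replicates.

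The arrays had similar overall signal, with median intensities between 44.5 and 49.3. Probe-set values of arrays of one group differed with a standard deviation of 0.28 to 0.45 on the log2 scale, and those of arrays of different groups with 1.16 to 1.21. The first principal component held 86.6% of the variance. Arrays 1 and 2 of the fkh-labelled group were the closest pair, at 0.28, and had lower signals of the bioB hybridisation control (398 and 388) than the third (744) and the control arrays (662 and 621). The ratio of the 3' to the 5' probe set of actin, a measure of RNA and labelling quality, was 4.94, 4.30 and 3.37 in the fkh-labelled arrays and 2.47 and 2.54 in the controls. The corresponding eIF-4a ratio was 2.35, 1.81 and 1.68 against 1.53 and 1.55, and that of Act5C 2.12, 1.68 and 1.48 against 1.45 and 1.42. All 3 were higher in each fkh-labelled array than in either control. The Gapdh ratio was 1.56, 1.14 and 1.11 against 1.16 and 1.14 and did not separate the groups.

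The fkh probe set was measured first, because the transgene carries this gene. Its signal went against the label: it was 49.0 ± 8.5 (SD, n = 3) in the arrays labelled fkh-expressing and 125 ± 6.6 (SD, n = 2) in the controls. The log2 fold was -1.13 with a standard error of 0.17 (limma adjusted p = 0.0026), and all 3 arrays lay below both controls. The position of this probe set relative to the part of fkh in the transgene is not known here, and a probe set outside that part does not test the label. The time of sampling limits it too: all glands were dissected at 14 h, and fkh closer to the heat shock at 9.5 h was not measured. For these reasons the groups are called the arrays labelled fkh-expressing and the controls, and every direction below rests on the labels. The white gene has no probe set named here and was not analysed here.

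A large part of the transcriptome differed between the groups. Of 11261 probe sets tested, 2328 rose and 2104 fell in the arrays labelled fkh-expressing (limma, Benjamini-Hochberg adjusted p under 0.05), which is 39.4% of them. Here and below, rose and fell mean higher and lower in those arrays past this threshold. At least 2-fold changes were found for 1375 probe sets that rose and 1076 that fell, and at least 16-fold changes for 124 and 33. Counted as genes with 1 probe set each, 1783 of 8298 rose and 1604 fell, with 1075 and 814 at least 2-fold. The counts of each list below stand against these shares of all genes, and counts near them do not set a list apart. With the third fkh-labelled array alone, chosen after seeing the data, 1337 probe sets were higher and 1397 lower, or 1041 and 1069 genes. Some markers of other tissues and the actin 3' to 5' ratio differed between the same arrays that every list below compares. The largest falls among fat body and haemocyte markers were those of Obp44a (1704 against 6483) and NimC4 (222 against 912). The median log2 folds of these 2 lists were -0.59 and -0.39. Without control array 1 the numbers that fell were 1222 probe sets and 944 genes, and without control array 2 they were 1301 and 993.

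**Figure D1:**
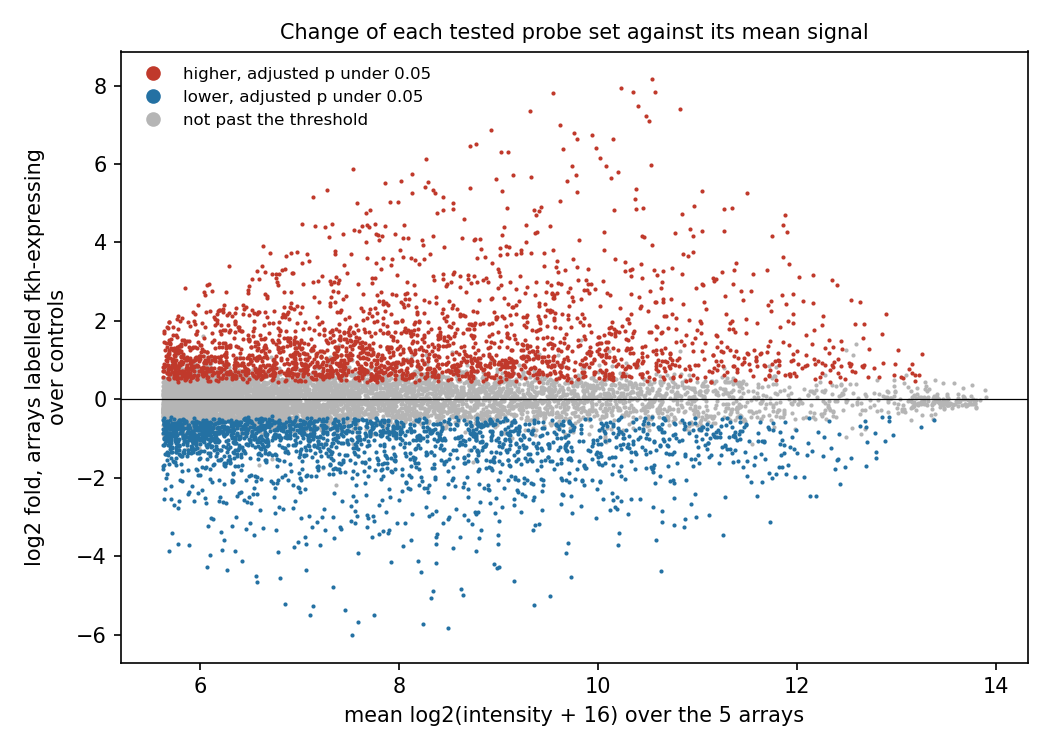
Each point is 1 of the 11261 tested probe sets, with its mean log2(intensity + 16) over the 5 arrays on the horizontal axis and the log2 fold of the arrays labelled fkh-expressing over the controls on the vertical axis. Red and blue points passed the adjusted p threshold, 2328 upward and 2104 downward; the largest rise of a named gene was 8.16 and the largest fall -5.82.

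The 12 largest rises ended at mean intensities between 2857 (CG31810) and 14301 (CG16826). CG16826 went from 34.1 ± 1.1 (SD, n = 2) in the controls to 14301 ± 318 (SD, n = 3), a log2 fold of 8.16 with a standard error of 0.14 (limma adjusted p = 3.5e-06). CG13135, CG34456, CG17362 and CG9451 had log2 folds of 7.93, 7.85, 7.84 and 7.80, and CG9040 7.39. The order depends on the constant added to each intensity, since several control means lay near it: CG9451 went from 13.2 to 6595, a larger ratio of intensities than that of CG16826. Cyp28d1, a cytochrome P450, rose by 7.10, CG30371 by 6.87, and ng4, a new glue gene of the salivary gland, by 6.79. CG3803, Acbp2 (an acyl-CoA binding protein) and CG31810 rose by 6.74, 6.63 and 6.51. For all 12 the 3 arrays lay above both controls. The signal of CG13135 varied between the controls, with a mean of 33.6 and a SD of 31.3, and that of CG31810 among the arrays labelled fkh-expressing, with a mean of 2857 and a SD of 1495.

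The largest falls were smaller. CG33181 went from 4017 ± 286 (SD, n = 2) in the controls to 55.6 ± 5.7 (SD, n = 3), a log2 fold of -5.82 with a standard error of 0.15 (limma adjusted p = 4.9e-06). CG3277, myd, CG31407, CG13050 and CG5966 had log2 folds of -5.72, -5.68, -5.50, -5.25 and -5.24. Here too the order depends on the added constant: CG31407 went from 1342 to 13.9, a larger ratio of intensities than that of CG33181. CG33127, CG1578, CG15097 and CG18128 lay between -5.05 and -4.79. Jhbp3, a juvenile hormone binding protein, had -4.88 and otu, a deubiquitinase first described in the ovary, -4.66.

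Most genes of salivary glue were higher in the arrays labelled fkh-expressing. The glue proteins are the main secretion of the larval gland, and Eig71E genes encode small secreted proteins of the late gland. Of 21 genes tested on this list, 10 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone. Sgs3 went from 867 ± 79 (SD, n = 2) to 5934 ± 95 (SD, n = 3), a log2 fold of 2.75 with a standard error of 0.15 (limma adjusted p = 3.1e-05). Sgs4 rose by 1.88 from 2203 to 8250.2, Sgs5bis by 5.26 from 322 to 12397, and Pig1 by 3.31 from 826 to 8313. The list as a whole shifted upward (limma camera with preset correlation, adjusted p = 0.0038), with a median log2 fold of 0.71. Its adjusted p was 0.64 with an estimated correlation, with which no list passed.

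The genes of this list did not move alike. Sgs1, Sgs5, ng1 and ng3, named after their values were seen, rose by 3.47, 3.64, 4.76 and 0.91. In a split made after the values were seen, 9 of the 12 Sgs, ng and Pig1 genes rose and 1 fell, with a median of 3.03. Sgs7, also named after its values were seen, fell by 0.58 (limma adjusted p = 0.042), and its adjusted p was 0.076, 0.098, 0.069 and 0.23 without fkh-labelled array 1, 2, 3 and control array 2. Of the 9 Eig71E genes tested only Eig71Ee, named after its values were seen, passed the threshold, with a log2 fold of 0.71, and its adjusted p was 0.057, 0.083, 0.062 and 0.19 without fkh-labelled array 1, 2, 3 and control array 1. The other 8 had intensities above 9000 in every array, close to the highest values on the arrays of 15488 to 16327, where a rise has little room to show. The groups differed as well in the actin 3' to 5' ratio (3.37 to 4.94 against 2.47 and 2.54) and in some markers of other tissues. The largest falls among fat body and haemocyte markers were those of Obp44a (1704 against 6483) and NimC4 (222 against 912).

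**Figure D2:**
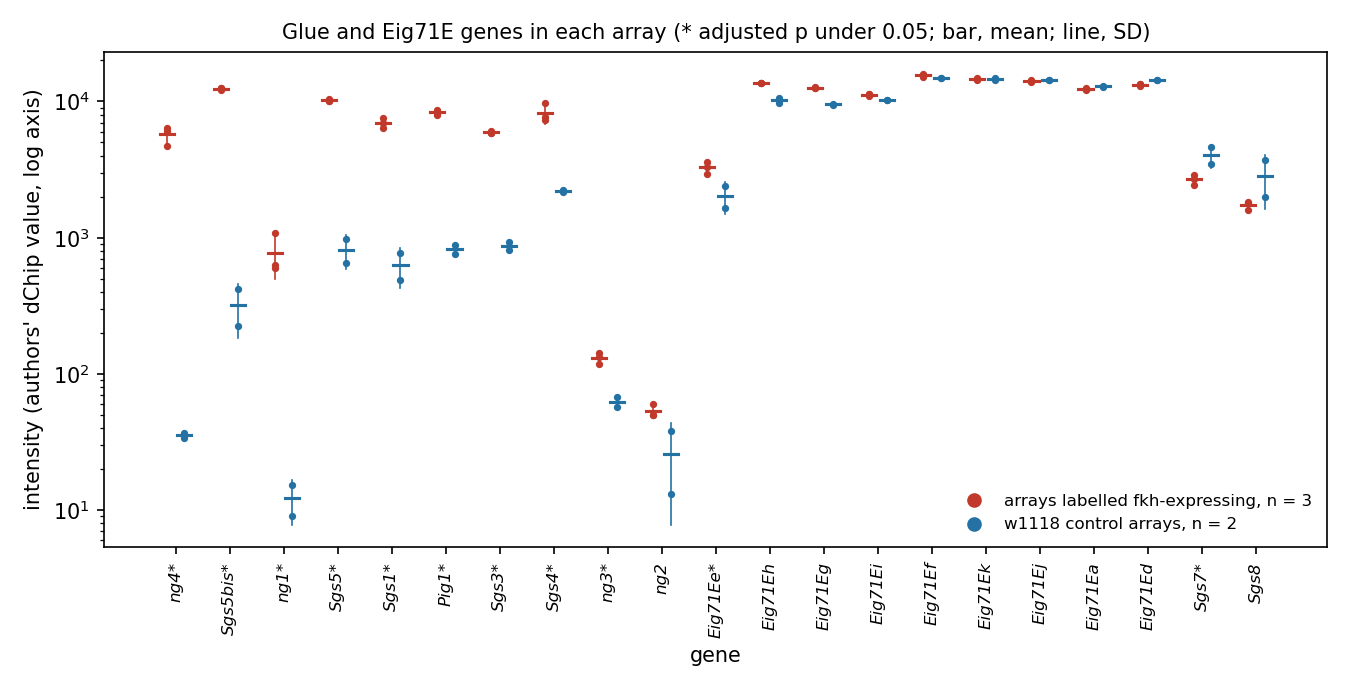
Intensity (authors' value, log axis) of each glue and Eig71E gene in the 3 arrays labelled fkh-expressing (red) and the 2 controls (blue), with mean (bar) and SD (line); an asterisk marks an adjusted p under 0.05. Sgs3 lies near 5934 in the red arrays and near 867 in the blue ones, while 8 Eig71E genes lie above 9000 in every array.

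Regulators of the salivary gland moved in both directions. Of 10 tested genes on the list of gland regulators and Fkh-linked genes, 4 rose and 2 fell, also when adjusted over the list alone. The transcription factor sage, which acts with fkh in the embryonic gland, rose from 552 ± 63 (SD, n = 2) to 2705 ± 396 (SD, n = 3), a log2 fold of 2.25 with a standard error of 0.19 (limma adjusted p = 0.00020). The zinc-finger factor sens rose by 3.00, the apical polarity gene crb by 1.79, and hry, named after its values were seen, by 0.86. The secreted signal fog had a log2 fold of -2.52. The log2 fold of eyg, named after its values were seen, was -1.10, and its adjusted p was 0.060 without control array 2. The list did not pass the threshold against other genes (camera adjusted p = 0.20), but moved upward on balance by fry (adjusted p = 0.012). CrebA was not analysed here.

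Several components of the cell death machinery were lower in the arrays labelled fkh-expressing. Of 18 tested genes on the cell death list, 9 fell and 3 rose, also when adjusted over the list alone. The initiator caspase Dronc fell from 4587 ± 437 (SD, n = 2) to 1779 ± 315 (SD, n = 3), a log2 fold of -1.37 with a standard error of 0.20 (limma adjusted p = 0.0022). Dark, the adaptor that activates Dronc, had a log2 fold of -1.16 at its brightest probe set, and its other probe set -0.58 with a standard error of 0.41 (adjusted p = 0.31). The caspase Strica and the tumour necrosis factor egr had log2 folds of -1.91 and -1.28. Corp, a regulator of p53, had -4.38, with means of 525 and 9816. Debcl, a Bcl-2 family member, rose by 1.42. Buffy, another Bcl-2 family member, and Drp1, a mitochondrial fission factor, were named after their values were seen and rose by 0.90 and 1.42. With each array left out in turn, all 3 rises and 5 of the 9 falls were called each time. The falls of crq, Dredd, p53 and wgn, named after their values were seen, were not, and without control array 1 their adjusted p was 0.14, 0.082, 0.14 and 0.12. The list did not pass the threshold against other genes (camera adjusted p = 0.17), but moved downward on balance by fry (adjusted p = 0.012). The actin 3' to 5' ratio (3.37 to 4.94 against 2.47 and 2.54) and some markers of other tissues differed between the same arrays. Among fat body markers the largest fall was that of Obp44a (1704 against 6483). The signal of grim was 13.6 and 14.3 on average, under the filter, and hid, rpr, Diap1 and Drice were not analysed here.

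**Figure D3:**
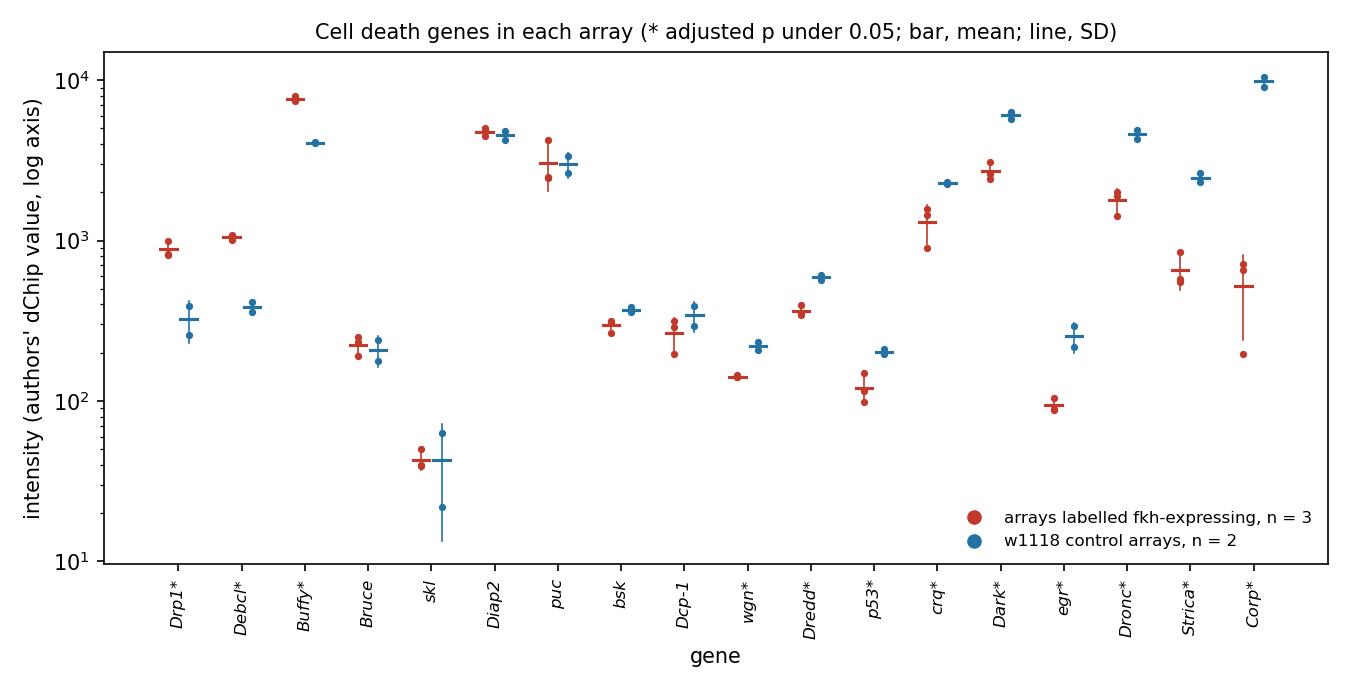
Intensity (authors' value, log axis) of each tested cell death gene in the 3 arrays labelled fkh-expressing (red) and the 2 controls (blue), with mean (bar) and SD (line); an asterisk marks an adjusted p under 0.05. Dronc averages 1779 in the red arrays and 4587 in the blue ones, and Debcl 1050 and 384.

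Autophagy genes went both ways. Of 24 tested, 6 rose and 7 fell, also when adjusted over the list alone, beside 1783 and 1604 of all 8298 genes. Atg13, part of the kinase complex that starts autophagy, fell from 5643 to 2757 (log2 fold -1.03, standard error 0.14, limma adjusted p = 0.0019). Atg4b and Atg18a had log2 folds of -1.47 and -0.97, and Atg16 0.90. Atg1, the kinase of that complex, rose by 0.89 with a standard error of 0.24 (limma adjusted p = 0.027), and its adjusted p was 0.079 without fkh-labelled array 1, 0.079 without fkh-labelled array 2, 0.15 without control array 1 and 0.073 without control array 2. With each array left out in turn, the rise of Atg16 and the falls of Atg13, Atg18a and Atg4b were called each time. Without either control array 2 of the 6 rises and 3 of the 7 falls were still called. The list did not pass the threshold as a whole (camera adjusted p = 0.36).

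Genes of the ecdysone response, the steroid hormone pathway of metamorphosis, were also split. Of 29 tested, 6 rose and 9 fell, and 6 and 10 when adjusted over the list alone. The ecdysone receptor EcR rose from 780 ± 27 (SD, n = 2) to 1807 ± 293 (SD, n = 3), a log2 fold of 1.18 with a standard error of 0.19 (limma adjusted p = 0.0031). The methionine sulfoxide reductase MsrA rose by 1.77, and the probe set annotated as asRNA:Eig63F-2, an antisense RNA, by 2.99. The nuclear receptors Hr38 and Eip78C had log2 folds of -3.85 and -2.17. Hr38 averaged 9.9 and 375, and was under the filter without control array 2. With each array left out in turn, 4 of the 6 rises (EcR, Hr78, MsrA and asRNA:Eig63F-2) and 2 of the 9 falls (Eip78C and ImpE1) were called each time, Hr78 and ImpE1 being named after their values were seen. Without control array 1 only 3 of the 9 falls were called, and without control array 2 only 2. The list did not pass the threshold as a whole (camera adjusted p = 0.51).

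Among the stage-specific factors on this list, the probe sets of one gene differed. At its brightest probe set, Eip93F, which acts upstream of gland cell death, had a log2 fold of -0.59 with a standard error of 0.19 (limma adjusted p = 0.047), and at its other probe set 0.65 with a standard error of 0.25 (adjusted p = 0.087). The adjusted p of the first was 0.12 without fkh-labelled array 1, 0.066 without fkh-labelled array 3, 0.15 without control array 1 and 0.17 without control array 2. The 5 probe sets of br had log2 folds from 0.39 to 1.35, of which those at 1.02 and 1.35 passed the threshold and the brightest, at 0.39, did not (adjusted p = 0.16). The brightest probe set of ftz-f1 had a log2 fold of -0.093 (adjusted p = 0.84) and its other one -0.75 (adjusted p = 0.036). Eip74EF and Eip75B were not analysed here.

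Proteasome genes rose where they changed. Of 31 tested, 16 rose and 0 fell, also when adjusted over the list alone, and the list shifted upward (camera adjusted p = 0.0058) with a median log2 fold of 0.56. Its adjusted p was 0.76 with an estimated correlation and 0.15 in the third fkh-labelled array alone. Rpt5 and Rpn6, subunits of the regulatory particle, rose by 2.14 and 0.95 (limma adjusted p = 0.00025 and 0.0029). Rpt3R and Prosbeta2R1, paralogues of proteasome subunits, rose by 1.82 and 2.74 from means of 7.9 and 5.5, and both were under the filter in some fits with an array left out. With each array left out in turn, 5 of the 16 rises were tested and called each time, and without control array 1 7 of them were. Some fat body markers, with the largest fall for Obp44a (1704 against 6483), and the actin 3' to 5' ratio (3.37 to 4.94 against 2.47 and 2.54) differed between the same arrays.

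Of 38 secretory pathway genes, 9 rose and 1 fell, and 4 and 0 when adjusted over the list alone. The signal recognition particle genes Srp19 and Srp72 rose by 1.98 and 1.65 (limma adjusted p = 0.00027 and 0.00038), and the coatomer gene epsilonCOP by 0.96. These 3 were the only rises of the list called with each array left out. Of the 9, 4 were called without fkh-labelled array 1, 5 without fkh-labelled array 2 and 3 without either control array. The log2 fold of eca, named after its values were seen, was -0.59, and its adjusted p was 0.078, 0.098 and 0.19 without fkh-labelled array 1, fkh-labelled array 2 and control array 1. The list missed the threshold as a whole (camera adjusted p = 0.078) and passed it without fkh-labelled array 3 (0.032) and without control array 1 (0.031). Of 12 heat shock genes, 3 rose and 1 fell, and 2 and 1 when adjusted over the list alone. The small heat shock gene Hsp27 rose by 1.16, from 6025 to 13483, and Hsf, the factor that activates heat shock genes, fell by 1.42. Hsp110 and stv rose by 0.70 and 1.17. Both calls were lost without control array 1 (adjusted p = 0.11 and 0.27), that of Hsp110 without control array 2 (0.082), and that of stv without fkh-labelled array 1 or 2 (0.12 each). The list did not pass the threshold as a whole (camera adjusted p = 0.49). Both groups had been heat shocked. Hsp22, Hsp23, Hsp83 and the listed Hsp70 genes had no probe set of 1 symbol and were not analysed here. The list therefore cannot tell whether the response to heat shock was alike in the groups.

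Of 18 insulin and TOR pathway genes, 6 rose and 2 fell, also when adjusted over the list alone. The list did not pass the threshold against other genes (camera adjusted p = 0.36), but moved upward on balance by fry (adjusted p = 0.012). Its median log2 fold was 0.22 and its mean 0.69. Tsc1, an inhibitor of TOR, rose by 4.72 from 244 ± 53 (SD, n = 2) to 6825 ± 1209 (SD, n = 3), and the kinase Pdk1 and the factor Mondo rose by 3.25 and 2.98. The cap-binding factor eIF4E1 fell by 2.14. The log2 fold of foxo, named after its values were seen, was -0.58, and its adjusted p was 0.058, 0.072, 0.057 and 0.13 without fkh-labelled array 1, fkh-labelled array 2, control array 1 and control array 2. Antimicrobial and immune genes were split, with 9 of 31 higher and 8 lower past the threshold, also when adjusted over the list alone. This list did not pass against other genes (camera adjusted p = 0.92), but moved upward on balance by fry (adjusted p = 0.0086). Its median log2 fold was 0.0030 and its mean 0.35, so that balance is not a rise of most of its genes. The lysozyme LysP rose by 4.43, pirk, an inhibitor of the Imd pathway, by 3.28, and spz, the Toll ligand, by 2.81. Of the 9 rises 7, and of the 8 falls 5, were called with each array left out. Def, a defensin, had a log2 fold of -4.20 and a control SD of 1458 around a mean of 3004.

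Of 79 genes of cytochromes P450, glutathione transferases and UDP-glycosyltransferases (Ugt), 25 rose and 16 fell, and 27 and 18 when adjusted over the list alone. The list did not pass the threshold against other genes (camera adjusted p = 0.49), but moved upward on balance by fry (adjusted p = 0.012). Its median log2 fold was 0.11 and its mean 0.35. Beside Cyp28d1, the rises of GstD5 (4.88), GstE11 (4.82) and Cyp12a4 (2.61) had the smallest p-values. Ugt317A1 and Ugt37C1 (1.40 and 1.03) and Cyp40, a cyclophilin that the list took in by its symbol, also rose, and Ugt36D1 had a log2 fold of -2.20, all 4 named after their values were seen. With each array left out in turn, 15 of the 25 rises and 9 of the 16 falls were called each time. Members of such families can be close in sequence, so probe sets may share signal between them. Among 64 respiratory chain genes 9 rose and 3 fell, and 7 and 2 when adjusted over the list alone (camera adjusted p = 0.36). COX5BL, ND-B8, ND-ACP and COX5B rose by 3.79, 3.39, 3.03 and 1.60. The 3 that fell, named after their values were seen, were ATPsynC (-1.20), ATPsynCF6L (-0.75, adjusted p = 0.063 without control array 2) and ND-13B (-0.62, adjusted p = 0.18 without control array 1). Of 18 glycolysis and TCA cycle genes 2 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.46). Trehalase (Treh), Idh and the bisphosphatase gene fbp had log2 folds of -2.71, -1.52 and -0.99, and Pepck1 rose by 1.27. Hex-A, named after its values were seen, rose by 0.53, and its adjusted p reached 0.17 without control array 1. Of the 6 falls 3 were called with each array left out. Of 24 lipid metabolism genes 4 rose and 5 fell, and 5 and 6 when adjusted over the list alone (camera adjusted p = 0.51). Pect and Lpin, which act in the synthesis of phospholipids and fats, had log2 folds of -3.67 and -3.32, and Acsl and Lip4 rose by 1.72 and 1.51. The others were named after their values were seen: whd (1.35) and SREBP (1.07) rose, and Lsd-1 (-0.84), Lsd-2 (-0.78) and Mtpbeta (-0.91) fell, with adjusted p of 0.11, 0.14 and 0.071 without control array 2.

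Ribosomal protein genes differed little. None of 36 tested passed the limma threshold, 0 had an unadjusted p under 0.05, and their log2 folds lay between -0.25 (RpL37-1) and 0.30 (RpL22-like), with a camera adjusted p of 0.46. With a trended and robust variance model RpL37-1 passed (adjusted p = 0.032). Most of these probe sets lay above 9000 in the controls, near the top of the intensity range. Of 68 mitochondrial ribosomal protein genes 10 rose and 9 fell, and 10 and 8 when adjusted over the list alone. Their median log2 fold was -0.012, their mean 0.044 and the camera direction upward (adjusted p = 0.92). mRpS6 and mRpS5 rose by 1.47 and 1.23, and mRpL27 and mRpL52 had log2 folds of -1.39 and -0.94. With each array left out in turn, 5 of the 10 rises and 2 of the 9 falls were called each time, the falls being those of mRpL27 and mRpL52. Of 41 lysosome and V-ATPase genes 5 rose and 5 fell, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.92). The lysosomal transporter spin and VhaM9.7-a rose by 2.06 and 2.05, and the thioesterase Ppt2 had a log2 fold of -1.26. Vha36-3 rose by 0.83, with an adjusted p of 0.058 without control array 1. The other members were named after their values were seen. Mitf and Cln3 rose, and without control array 2 their adjusted p was 0.082 and 0.18. CtsL1, VhaAC39-1, VhaAC45 and VhaM9.7-c fell, and without control array 1 their adjusted p was 0.12, 0.14, 0.061 and 0.21.

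Marker genes of other tissues that a dissected gland could carry were mostly lower in the arrays labelled fkh-expressing where they changed. Of 65 cuticle, trachea and epidermis markers 21 fell and 4 rose, also when adjusted over the list alone, with a median log2 fold of -0.31 and a camera adjusted p of 0.034. That adjusted p was 0.64 with an estimated correlation, 0.063, 0.0502 and 0.12 without fkh-labelled array 1, fkh-labelled array 2 and control array 2, 0.16 with no filter on low values and 0.069 after quantile normalization. The chitinase Cht5 fell from 825 to 269, verm from 953 to 307 and Pcp from 1200.4 to 502. Of the 21 falls 8 were called with each array left out, 11 without fkh-labelled array 1 or control array 1, and 10 without fkh-labelled array 2 or control array 2. The 4 cuticle protein genes that rose, named after their values were seen, were Cpr65Ea (0.99), called with each array left out, Cpr49Ad (0.71), Cpr49Af (0.71) and Cpr78Cb (1.10). The call of Cpr49Ad was lost without control array 2 (adjusted p = 0.077), and those of Cpr49Af and Cpr78Cb without control array 1 (0.091 and 0.089). Of 12 fat body markers 5 fell and 0 rose, and of 13 haemocyte markers 5 fell and 0 rose, both also when adjusted over the list alone. Both lists moved downward on balance by fry (adjusted p = 0.017 and 0.013), as the cell death list did. Neither list shifted by camera (adjusted p = 0.088 and 0.10), although that of the fat body was 0.031 without control array 1. Obp44a had a log2 fold of -1.94, Obp99b -1.49, Apoltp -1.03, Fbp1 -0.94 and Lsp2, named after its values were seen, -0.54. In the controls Obp99b and Obp44a were bright, with means of 13157 and 6483, and Apoltp was dim, with 94.0. Whether the gland itself expresses such markers was not tested, so their falls need not mean less of another tissue. The adjusted p of Obp99b, Fbp1 and Lsp2 was 0.076, 0.0502 and 0.12 without control array 2. NimC4, a phagocytic receptor, had -1.97, NimC1 -0.92, Glt -0.80, Ppn -0.66 and srp, named after its values were seen, -0.59. Without control array 1 the adjusted p of NimC1, Glt, Ppn and srp was 0.056, 0.051, 0.10 and 0.12.

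Of 13 muscle markers 2 rose and 2 fell, and 1 and 2 when adjusted over the list alone (camera adjusted p = 0.61). Act79B had a log2 fold of -1.39, and Prm averaged 58.9 against 134, with an adjusted p of 0.058 without control array 1. Mlp60A and Zasp52 rose by 0.76 and 0.96, with adjusted p of 0.081 without control array 2 and 0.27 without control array 1. Of 13 neuronal and glial markers 1 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.23, and 0.033 without control array 1). The glial gene moody went from 2541 to 268, a log2 fold of -3.17. The neuronal genes elav and nSyb had -1.35 and -0.76, and Rdl rose by 0.58. The adjusted p of nSyb and Rdl was 0.083 and 0.14 without control array 1. Of 15 gut and Malpighian tubule markers 1 rose and 2 fell, and 1 and 1 when adjusted over the list alone (camera adjusted p = 0.49). Mur18B had a log2 fold of -3.14, iotaTry -0.67 and Nha1 1.01, with adjusted p of 0.11 for iotaTry without control array 2 and 0.10 for Nha1 without control array 1. Of 22 cell cycle and DNA replication genes 2 rose and 7 fell, and 2 and 9 when adjusted over the list alone (camera adjusted p = 0.053, and 0.031 without control array 1). The replication genes RPA1 and PCNA had log2 folds of -1.57 and -1.28, and fzy, an activator of the anaphase-promoting complex, rose by 1.75. CycD, named after its values were seen, rose by 0.55, and its adjusted p reached 0.17 without control array 1. Of the 7 falls only those of RPA1 and PCNA were called with each array left out. A further list, on X dosage and sex, had fewer than 5 genes left after the filter and was not tested.

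**Figure D4:**
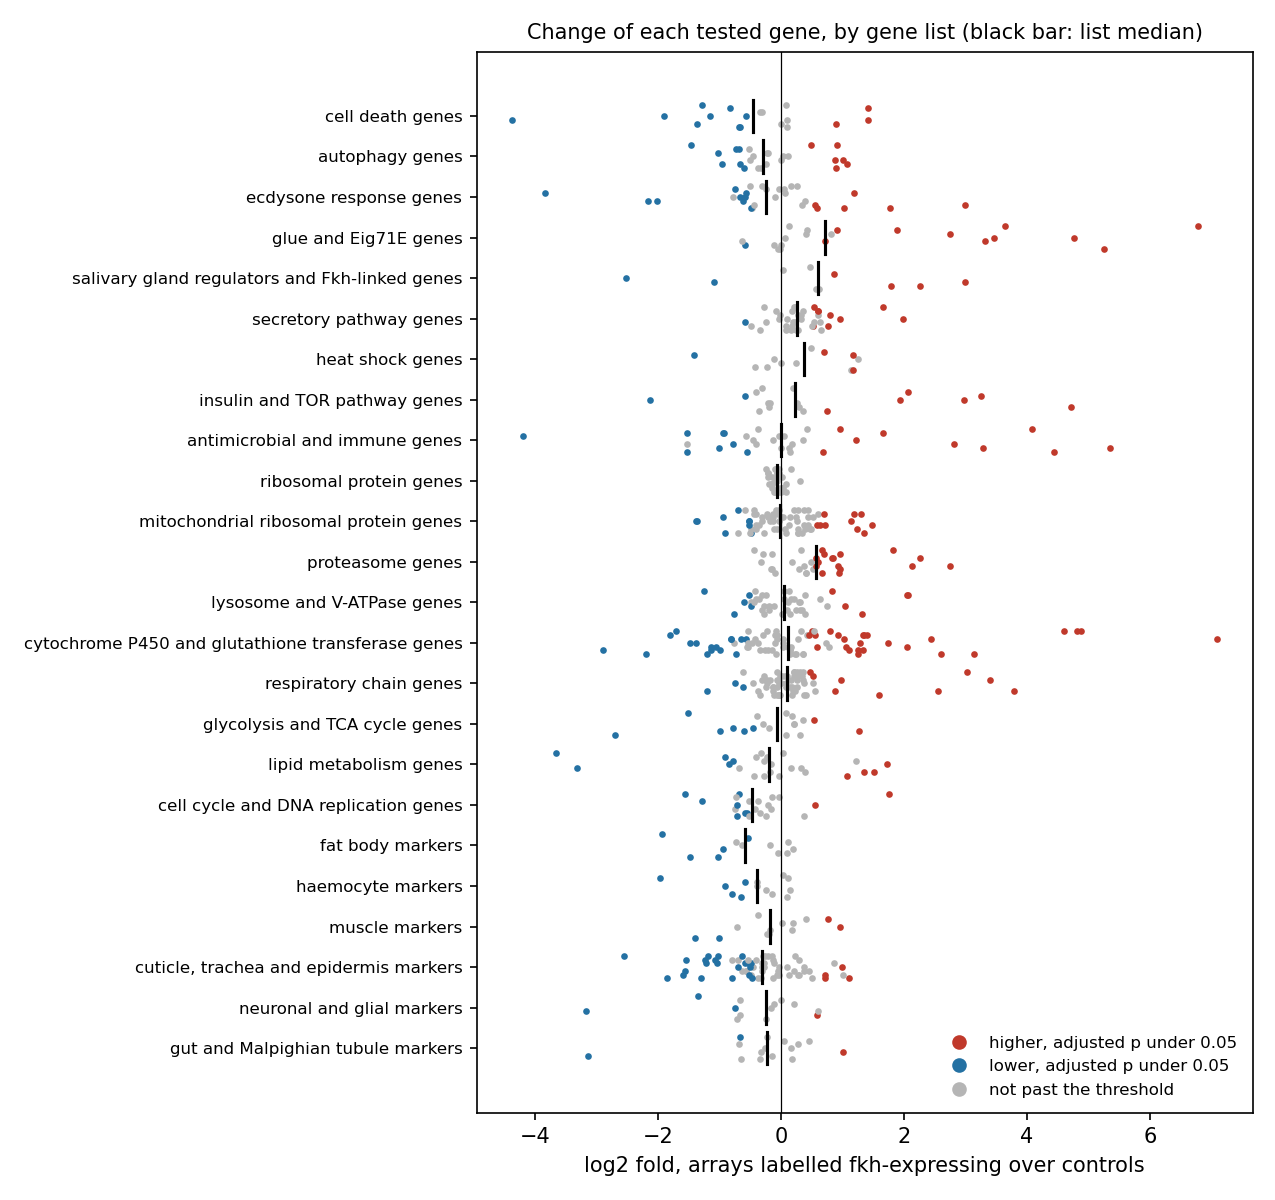
Each point is a tested gene, placed by its log2 fold of the arrays labelled fkh-expressing over the controls, in 24 gene lists; red and blue points passed the adjusted p threshold and black bars are list medians. The glue and Eig71E list has a median of 0.71 and reaches 6.79, and none of the 36 ribosomal protein genes passed the threshold. The cytochrome P450 list includes the Ugt genes.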

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

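The tests of the strain variants, the hybridisation batch with its simulation and its comparison with the other control, the exchanged labels, the other tissues and the stage given in this part were chosen after the results they bear on had been seen, and the restriction to 13 glue and Eig71E genes after the value over all of them.

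Of 183 control probe sets, which were left out of the tests of genes, 3 had a signal at least 4-fold above the control arrays in the arrays labelled fkh-expressing (limma adjusted p under 0.05 over the control probe sets). AFFX-Dm-J01636-2_s_at had a log2 fold of 3.39, with means of 161 and 0.84. AFFX-Dm-U89963-1_x_at had 3.76, with means of 252 and 3.4. AFFX-r2-Bs-thr-3_s_at, named for a Bacillus subtilis gene, had 2.15, with means of 2482 and 553. In each case all 3 arrays lay above both controls.

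The lower signal of the fkh probe set bears on whether the labels of the groups were exchanged. If they had been, probe sets for foreign sequence carried by a transgene construct would be higher in the arrays labelled control. Of 100 control probe sets in the AFFX-Dm series, 2 were at least 4-fold higher in the arrays labelled fkh-expressing and 0 were 4-fold lower, but AFFX-Dm-Q9LFR4_at (3.3 against 33.2, log2 fold -1.36), AFFX-Dm-Q9LVE8_at (2.4 against 25.0, log2 fold -1.17) and AFFX-Dm-U43284-1_s_at (log2 fold -0.95) were called lower, the first 2 kept under 4-fold by the added constant, and AFFX-Dm-J01636-1_at and AFFX-Dm-J01636-3_at had -0.60 and -0.66 (adjusted p = 0.27 and 0.23). The sequences of these probe sets and of the transgene construct were not used here, and their names mark possible cross-hybridisation, so correct and exchanged labels cannot be told apart from these values. An fkh probe set outside the transgene, with lower signal of the resident gene, stays open and was not tested. The fkh signal between the heat shock and the dissection at 14 h was not measured.

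Of the technical explanations for the changes of at least 2-fold, sequence variants between the strains under the probes would change single probe sets and leave other probe sets of the same gene near 0. Of 1889 genes changed at least 2-fold, 151 had other probe sets, and these 200 probe sets had a median log2 fold of 0.95 in the direction of the main probe set, with a 95% bootstrap interval from 0.78 to 1.20, against 1.72 for the main probe sets, and 165 had the same sign while 10 were called in the opposite direction, which argues against variants as the general cause among these 151 genes, though not for single genes or a part of the change, and leaves the other genes untested. A hybridisation batch of fkh-labelled arrays 1 and 2 would leave the third array near the controls, but of 2518 probe sets called at least 2-fold without it, 2485 passed the filter with all 5 arrays and 97.8% of these lay beyond both controls in it in the same direction, against 36.9% to 39.7% in 20 simulations with the third array at the controls' level. With probe sets called against control array 1 or 2 alone, the third array differed from the other control by a median log2 of 1.51 and 1.54 in that direction, which argues against such a batch as the general cause. RNA quality (actin, eIF-4a and Act5C 3' to 5' ratios higher in the arrays labelled fkh-expressing, that of Gapdh not), genetic background and any handling shared by a group stay open beside the transgene, since each goes with the group.

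Higher glue signal could come from fewer cells of other tissues, some of whose markers were lower. That would raise all gland transcripts by about the same factor. Of the 13 genes of the glue and Eig71E list that were not above 9000 in every array, 7.69% (1 gene) lay within 3 standard errors of their median of 2.75. That gene was Sgs3, itself the median, so the test could give no lower share. The constant and the top of the range can also spread folds under a common factor. Sgs3 and Sgs7, with control means of 867 and 4043 away from both limits, had log2 folds of 2.75 and -0.58. A common factor does not account for these 2, which were picked after their values were seen. A difference in stage between the groups stays open: the ecdysone response list had a camera adjusted p of 0.51 with members called in both directions, and no stage series was used here, so a stage difference and an effect of the transgene cannot be told apart. The transgene itself remains the explanation the design names.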

How the results depend on the processing

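The alternatives were set before the data were examined, except the 2 on fkh-labelled arrays 1 to 3 (the third alone, and the first 2 averaged), which were chosen after seeing the data. Of 2331 values of 148 named genes over 16 settings, 2184 kept their side of the threshold and 145 kept the direction but lost the call. Among the 2184, values called in neither fit were counted whatever their direction, and ftz-f1 changed direction without control array 2. Another 1 gained a call, and 1, Eip93F with the mean over its probe sets, turned to 0.025 (limma adjusted p = 0.93), since its probe sets differ in sign. RpL37-1 gained its call with the trended and robust variance model. Most of the 148 were taken for the size or the small p of their change, so these counts do not describe called genes in general. Some genes named above, such as crq, Dredd, p53 and wgn, are not among the 148. No probe set called both above and in an alternative had opposite directions. The median over all probe sets was -0.050 after quantile normalization and 0.038 after median centring. The white gene gave no value in any setting, and some dim named genes fell under the filter in some.

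The third fkh-labelled array alone gave 1337 probe sets higher and 1397 lower, 1041 and 1069 genes, and 1 list. Where 1 array of a group was left, it was assumed to vary like the other group. Leaving out each array in turn gave 1222 to 2309 lower probe sets, 944 to 1740 lower genes and 2 to 7 lists, with the most lower probe sets without fkh-labelled array 3. Genes tested and called each time numbered 1031 higher and 738 lower.

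List results depended most on the test. With an estimated correlation 0 lists passed (glue 0.641, proteasome 0.760, cuticle 0.641). There the camera adjusted p of the fat body list went from 0.0881 to 0.641, although its estimated correlation of -0.034 lay below the preset 0.01. A loss with this test thus need not reflect correlation between the genes of a list. No list had an adjusted p below 0.641 with it, so it cannot decide about single lists. With fry 13 lists passed, among them cell death, gland regulators, insulin and TOR, P450 with transferases, and respiratory chain (each adjusted p 0.0124), immune 0.00859, glycolysis 0.0390, cell cycle 0.0352, fat body 0.0169 and haemocyte 0.0130. The cuticle list gave 0.159 with no filter, 0.0687 after quantile normalization, 0.151 in the third array, 0.0530 with arrays 1 and 2 averaged, and 0.0207 to 0.123 with arrays left out. The proteasome list gave 0.151 in the third array and 0.0030 to 0.028 with arrays left out, and the glue list 0.0011 to 0.011. The secretory list passed with no filter (0.0319), and gave 0.0314 to 0.311 with arrays left out. The cell cycle list passed with a constant of 1 (0.0388) and with the mean over probe sets (0.0471), and gave 0.0314 to 0.105 with arrays left out. The fat body list gave 0.0314 to 0.139 and the neuronal list 0.0327 to 0.318 there. The cause of these changes was not tested.

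With the replicate block 2350 probe sets were higher and 2019 lower, and the secretory list passed (0.0367). Only 2 numbers are shared, and nothing says that they mark a shared day. Arrays of one number deviated from their group means with correlations of 0.077 and -0.11. The deviations of the 2 controls mirror each other (correlation -1), so these correlations cannot tell whether a day was shared. Signal limits the rest: dim genes are compressed by the constant and bright ones by the top of the range.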

Other observations

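The tests of gene families were chosen after other results had been seen; those of neighbouring genes were set down before their counts were known.

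All 6 tested genes of the juvenile hormone binding protein family fell. Jhbp3 had the largest change, from 2494 ± 599 (SD, n = 2) in the controls to 67.8 ± 4.9 (SD, n = 3). Jhbp2, Jhbp1, Jhbp12, Jhbp5 and Jhbp7, named after their values were seen, had log2 folds of -2.10, -1.55, -1.32, -1.04 and -0.62. The arrays labelled fkh-expressing lay below both controls for each. Among 101 families grouped by the letters that start a symbol, each tested in both directions, it alone passed Fisher's exact test after adjustment over the 202 tests (adjusted p = 0.0105). That test counts all 6 genes as called, Jhbp7 among them. It was not repeated without Jhbp7, so the family result depends on a call that was not stable. The call of Jhbp7 was lost without fkh-labelled array 1 (adjusted p = 0.093), fkh-labelled array 3 (0.054), control array 1 (0.091) and control array 2 (0.20). The actin 3' to 5' ratio (3.37 to 4.94 against 2.47 and 2.54) differed between the same arrays. So did 5 of 12 fat body markers, with the largest called falls for Obp44a (-1.94) and Obp99b (-1.49). The chitinase (Cht) family, with 5 of 8 genes lower past the threshold, and the Rpt and Rpn proteasome families, with 5 of 6 and 6 of 10 higher, did not pass (adjusted p = 0.30, 0.23 and 0.30).

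Genes that changed at least 2-fold lay beside each other more often than random placement gives. Of 5444 pairs of adjacent protein-coding genes in the RefSeq gene table with both members tested, 189 had both members higher, against a median of 95 and a 95% range of 78 to 112 in 10000 random placements (permutation p = 1e-04, the smallest they can give). In 97 pairs both were lower, against a median of 52 and a 95% range of 39 to 65 (permutation p = 1e-04, again the smallest possible). Placements among genes of like mean signal gave medians of 97 and 52. Overlapping transcripts and probe sets that share signal between tandem paralogues were not separated from these counts. Runs of 5 adjacent genes that rose were GatB, Tsc1, Sec10, Npc2f and Kal1, and CG12698, Muc14A, CG12395, dpr18 and Nipsnap. Runs of 5 that fell were Plc21C, CG11912, CG11911, CG33127 and CG43755, and CG5359, Mical, CG31407, CG3909 and CG11722. GstD4, GstD5, GstD6 and GstD7 made a run of 4 that rose. Some of these genes were not called with each array left out. Without control array 1 the adjusted p of CG12395, dpr18, CG11722 and GstD7 was 0.27, 0.14, 0.052 and 0.052. The calls of CG12395, dpr18 and GstD7 were also lost without fkh-labelled array 1 (0.12, 0.079 and 0.10) or 2 (0.12, 0.079 and 0.10), and those of dpr18 and GstD7 without control array 2 (0.11 and 0.22). GstD6 was under the filter without fkh-labelled array 1 or 2, and CG11911 without either control array. The runs were picked after their values were seen.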
